A study of Mus musculus with 6 samples.

How the data were processed

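Total RNA of mouse spleen was labelled with Cy3 and hybridised to single-colour Agilent arrays, 1 array per sample, with 3 model and 3 CMP samples. Groups were taken from the sample titles and treatment labels. The labels give spleen as the tissue, whereas the extraction text in the same labels describes liver; spleen was kept because the title, source and tissue labels all give it, and markers of liver were among the lists tested. All samples are labelled male.

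Per the file headers, the scanner images were read with Agilent Feature Extraction 11.0.1.1, the version that the submitters' processing notes also name. The deposited processed signal is an intensity on a linear scale after background subtraction and spatial detrending, with low values replaced by a surrogate, and it is not normalised between arrays, per the file headers. The authors also deposited a table of log2 values for the same arrays. Its columns correlated with the log2 processed signal of their own array at 0.993 to 1.00, more closely than with any other array, so scale and direction are settled, and genes were not centred. Its column medians were 5.35 for all 6 arrays and the upper quartiles were 8.60, as quantile normalisation gives; the method is not given in the sources used here. The array design is annotated on mm9, whereas the gene table used for names belongs to GRCm38.p6, so no coordinates are given.

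Each array holds 43020 non-control spots of 39429 probes. Outlier spots were left out, spots of a probe were averaged, and log2 of the processed signal minus the array's 75th percentile over non-control probes was used. The 75th percentile was 295 to 626 intensity units and the median 28.6 to 66.0. The number of arrays, 3 per group, limits the precision. A probe was kept where it was well above background on at least 3 of the 6 arrays, whatever their group, a probe with several spots counting as such where over 50% of them were. That left 24756 probes, of which 84 with a missing value on some array were left out. Probes were named by matching their accession without version to the gene table: 27234 probes matched a symbol and 12195 did not and keep their identifier. A gene was represented by its probe with the highest mean over all 6 arrays, which gave 20584 genes, 14442 with a symbol. For Cd6, Tcf4, Cflar and Cmpk2 another kept probe had the opposite sign. Of 1617 unnamed Ensembl transcripts 166 were called lower and 32 higher.

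The comparison of CMP with model was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment over all genes, threshold 0.05), on all 6 arrays with no covariate, and fold changes are CMP minus model on the log2 scale. A looser count used an unadjusted p under 0.05 and at least a 2-fold change. Fixed lists of marker and pathway genes, 24 in all with 556 different members, were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists. The test was repeated with an estimated correlation, under which 0 of the 11 lists that passed kept an adjusted p under 0.05. The fry test, which asks whether a list's genes move on balance in a direction and makes no comparison with other genes, was run beside it: 9 of these 11 lists passed in limma fry (adjusted p from 0.000112 to 0.0314), and the platelet (0.0543) and cell cycle (0.0602) lists did not.

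Where a probe was not well above background on any array of a group, the difference is given as a bound: the mean of the brighter group against the mean of, per array, the lowest signal among probes well above background or the probe's own signal where that is higher. The rule for named genes took the 12 genes with the largest and the 12 with the smallest log2 fold change among called genes with non-overlapping groups, passing over unnamed and predicted genes, the 4 members of smallest p in each list, and the largest bounds. Some genes that this rule takes are not reported here. The groups, the tests, the lists, this rule and most alternatives were fixed before the data were examined.

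Alternatives were a normexp background correction (offset 50), quantile normalisation, median scaling, the authors' log2 values, other filters on dim probes, the mean of a gene's probes, a trended robust variance, array weights, the replicate number as a block, the slide as a block, and leaving out each array. The normexp correction was planned on mean spot signals; median spot signals were used, because those are the raw signals in the files used. Chosen after seeing the data were fits of slide 1 alone, of 2 against 2 arrays, and a count without the genes that follow the E1A control probe. Slides were told apart by the shared scan record in the file headers.

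The programs were tested on simulated data. For the comparison of CMP with model, 10 simulations of 20584 genes with the measured variances held 200 changed genes each. The share recovered was 0.20% at a log2 change of 0.5, 21.4% at 1, 62.0% at 2 and 81.4% at 3, and 4.73% of all calls were false. The simulated arrays and genes were independent, whereas model replicate 2 and CMP replicate 3 may not be independent of the other arrays. The share of false calls therefore does not carry over to the measured calls. A shift given to the T cell list alone was found by camera in 10 of 10 simulations, with 0 other lists called at the preset correlation. With an estimated correlation it was also found in 10 of 10. The simulated genes were independent, whereas the estimated correlation in the measured T cell list was 0.48. These simulations therefore do not test false list calls among correlated genes. The estimate of blending weights returned 0.6 where that was simulated; 68.3% or more of 20337 probes lay between the sources for a simulated blend, and at most 33.7% for separate arrays.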

Results

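Gene expression was measured in the spleen of male mice on 6 single-colour oligonucleotide arrays, 3 for each of 2 groups. Every mouse of both groups had received cyclophosphamide, an alkylating drug that depletes dividing blood and immune cells, at 40 mg/kg a day for 2 days. The model group was given distilled water by mouth, and the CMP group was given Cordyceps militaris polypeptide, a peptide preparation from a medicinal fungus, at 800 mg/kg a day for 45 days. The series asks how CMP modulates immune function, and its design text states that the high-dose group was chosen for the arrays. The untreated mice and the lower doses were not analysed here, so each difference is between CMP and model mice and not a return towards a normal spleen. The labels name a time of 2 days for the model samples and 45 days for the CMP samples, and they do not say how long before sampling the drug was given in each group. Between 54.9% and 67.5% of the non-control spots of an array were well above background. The labels number the replicates and do not say that they came from separate animals, so p-values measure the spread between these samples, which may be technical.

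Lists of erythroid, plasma cell, platelet and cell cycle genes were lower in CMP than in model spleens, and lists of T cell and B cell genes were higher, by limma camera at its preset correlation. With an estimated correlation none of these 6 lists passed (limma camera adjusted p from 0.280 to 0.409), and 3 of 16 platelet and 4 of 32 cell cycle genes passed singly. At the preset correlation 4 to 10 of the 24 lists also passed when the arrays were split into 3 and 3 in other ways. Of 20584 genes tested, 402 were higher and 823 were lower in CMP at a limma adjusted p under 0.05, and 150 of the former and 642 of the latter differed by at least 2-fold. Without the adjustment, 788 genes were at least 2-fold higher and 1292 at least 2-fold lower at p under 0.05. The 3 arrays of each group did not overlap for 35.4% of the genes, and for all 1225 called genes. Chance would give 10% if all arrays were independent. That figure is too low a yardstick where an array lies between the others of its group, as described below. A symbol could be given to 307 of the higher and 513 of the lower genes. These calls depended on single arrays. The higher and lower counts were 13 and 145 without model replicate 1, 1502 and 1406 without model replicate 3, 102 and 525 without CMP replicate 1, and 2 and 50 without CMP replicate 3. Without model replicate 2 limma called 0 genes, with 3221 at unadjusted p under 0.05 and a smallest adjusted p of 0.0565, so no gene named here held its call in that setting. The count of genes at least 2-fold higher was 466 without model replicate 1, 469 without model replicate 2 and 1364 without model replicate 3. The direction of the 1225 called genes could not turn in these fits, because their groups did not overlap. Median scaling gave 584 higher and 651 lower genes, which raised the share of higher genes among all calls from 32.8% to 47.3%. Normexp background correction left 2 higher and 33 lower genes (5.71% higher), 34 of them among the 1225, and 32 and 218 passed without the filter on dim probes (12.8% higher). Normexp also moved the median of all genes from 0.04 to 0.20, so list medians given under normexp are relative to that.

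The arrays were not evenly spread over slides. Slide 1 held the 3 model arrays and CMP replicate 1, and slide 2 held CMP replicates 2 and 3. Slide 2 holds no model array, so each value given with slide as a block or within slide 1 compares CMP replicate 1 alone with the model arrays and leaves out CMP replicates 2 and 3. These 2 values are therefore not separate checks, and gene list p-values from them, which rest on 1 CMP array, are not given. With slide as a block limma called 5 genes higher and 100 lower. Within slide 1 alone it called 0 genes, with 5125 at unadjusted p under 0.05 and a smallest adjusted p of 0.0608. Signals of model replicate 2 lay between those of model replicates 1 and 3 for 79.9% of 20337 probes, and those of CMP replicate 3 lay between CMP replicates 1 and 2 for 73.7%. In a fit without these intermediate arrays, added after the data were seen, limma called 0 genes, with 1383 at unadjusted p under 0.05 and a smallest adjusted p of 0.430. The adjusted p-values of all 6 arrays therefore rest on samples that may not be independent.

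T cell genes stood higher in CMP. Of 24 tested members of the T cell list 8 rose and 16 did not pass, with a median log2 fold change of 0.76 (limma camera adjusted p = 2.5e-08; adjusted p = 0.404 with an estimated correlation). Adjusted over the list alone, 18 members were higher and 1 was lower. Il7r, the receptor chain for interleukin 7 that sustains resting T cells, rose from -0.75 ± 0.31 to 0.63 ± 0.16 (SD, n = 3), which is 2.60-fold. Bcl11b, a transcription factor of T cell commitment, rose 2.31-fold, and Trat1, an adaptor of the T cell receptor complex, rose 2.13-fold. Cd6, a T cell surface receptor, rose 1.84-fold on the probe used, whereas another kept probe of the gene gave a log2 fold change of -0.09.

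B cell genes were also higher. Of 20 tested members 6 rose and 14 did not pass, with a median of 0.51 (limma camera adjusted p = 1.6e-05; adjusted p = 0.280 with an estimated correlation), and 10 were higher when adjusted over the list alone. Pax5, the transcription factor that maintains B cell identity, rose 2.16-fold. Spib rose 1.81-fold, and Cxcr5, the chemokine receptor that guides B cells into follicles, rose from 3.07 ± 0.02 to 3.89 ± 0.04 (SD, n = 3). Cxcl13, the ligand of Cxcr5, rose 2.40-fold. In CMP replicate 1 alone, which is all that the fits with slide as a block and within slide 1 use, the medians were 0.85 for T cells and 0.55 for B cells.

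The lists of antigen presentation and of Toll-like receptor and NF-kB signalling passed limma camera with few single members passing. In the antigen presentation list 3 of 22 members rose (median log2 fold change 0.32; limma camera adjusted p = 0.000776; adjusted p = 0.133 with an estimated correlation), and 4 were higher when adjusted over the list alone. They were Ciita, the master regulator of class II histocompatibility genes, at 1.94-fold, the costimulatory receptor Cd40 at 1.97-fold, and H2-DMb1, which helps to load class II molecules, at 1.69-fold. Under a normexp background correction the antigen presentation list no longer passed (median 0.14, adjusted p = 0.585 with limma camera). In the Toll-like receptor and NF-kB list 1 of 29 members rose, also when adjusted over the list alone (median 0.23; limma camera adjusted p = 0.0142; adjusted p = 0.330 with an estimated correlation). That gene was Nfkb2, a subunit of the non-canonical pathway, at 2.26-fold. Without CMP replicate 1 this list had a limma camera adjusted p of 0.0607. With slide as a block, and within slide 1, both lists had a median of 0.25, from CMP replicate 1 alone.

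Plasma cell genes fell. Of 13 tested members 6 fell and 7 did not pass, with a median log2 fold change of -1.23 (limma camera adjusted p = 4.85e-10; adjusted p = 0.328 with an estimated correlation), and all 13 were lower when adjusted over the list alone. Tnfrsf17, the survival receptor of plasma cells, fell from -0.26 ± 0.03 to -3.97 ± 0.22 (SD, n = 3), a 13.1-fold drop with a limma adjusted p of 0.00296. Jchain, which links antibody monomers, fell 5.49-fold and Xbp1, a transcription factor of the secretory programme, fell 2.73-fold. Sdc1, the plasma cell surface marker, was not well above background on any CMP array and was at least 3.83-fold lower there. The median was -1.63 with slide as a block and within slide 1, from CMP replicate 1 alone.

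Erythroid genes were lower. Of 25 tested members 15 fell and 10 did not pass, with a median log2 fold change of -2.34 (limma camera adjusted p = 2.77e-13; adjusted p = 0.404 with an estimated correlation), and 24 were lower when adjusted over the list alone. Epb42, a red cell membrane protein, fell 8.46-fold, from 0.91 ± 0.92 to -2.18 ± 0.47 (SD, n = 3). Car2, a carbonic anhydrase, fell 4.83-fold, Tal1, a transcription factor of blood stem and erythroid cells, fell 3.93-fold, and Alas2, the first enzyme of haem synthesis in red cell precursors, fell 3.85-fold. The embryonic globin gene Hbb-bh1 fell 15.7-fold and was well above background on 1 of 3 CMP arrays. The list median against the model mean was -1.69 in CMP replicate 1, -3.07 in CMP replicate 2 and -2.17 in CMP replicate 3, and the model replicates themselves lay at 0.53, 0.20 and -0.68. With slide as a block, and within slide 1, the median was the -1.69 of CMP replicate 1.

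Platelet and megakaryocyte genes followed the same direction. Of 16 tested members 3 fell and 13 did not pass, with a median of -1.49 (limma camera adjusted p = 4.03e-08; adjusted p = 0.409 with an estimated correlation, and 0.0543 in limma fry), and 14 were lower when adjusted over the list alone. Gp1ba, a chain of the platelet receptor for von Willebrand factor, fell 8.95-fold, and the collagen receptor gene Gp6 fell 3.29-fold. The third, Selp, fell 1.55-fold with 2 of 3 CMP arrays well above background, but under normexp its log2 fold change was 0.28. The list median against the model mean was -0.75, -2.23 and -1.07 in CMP replicates 1 to 3, and it was -0.89 without CMP replicate 2 and, from CMP replicate 1 alone, -0.75 with slide as a block and within slide 1.

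**Figure D1:**
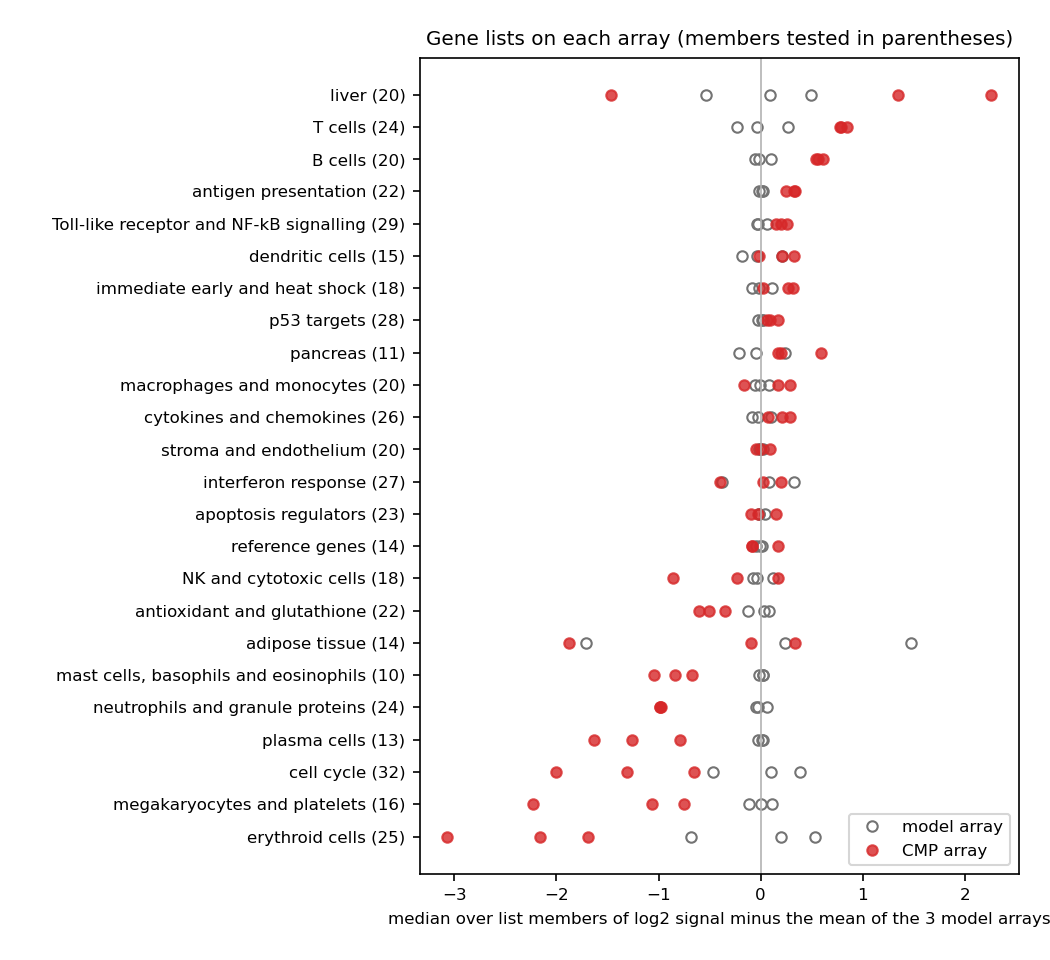
For each gene list, the horizontal axis gives the median over its tested members of the log2 signal minus the mean of the 3 model arrays, with open points for model arrays and filled points for CMP arrays. T cell medians of the CMP arrays lie between 0.78 and 0.85 and erythroid medians between -3.07 and -1.69, whereas the liver medians of the CMP arrays run from -1.46 to 2.26.

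Genes of granulocytes moved in both directions. Of 24 tested members of the neutrophil list 10 fell, 5 rose and 9 did not pass, with a median log2 fold change of -0.94 (limma camera adjusted p = 0.000661; adjusted p = 0.133 with an estimated correlation); adjusted over the list alone, 16 were lower and 6 higher. The 4 members of smallest p all fell. Elane, a serine protease of azurophil granules, fell 5.22-fold, from 5.91 ± 0.36 to 3.52 ± 0.25 (SD, n = 3), Prtn3 fell 3.93-fold, Chil3 fell 6.83-fold, and Lcn2, which binds bacterial iron carriers, fell 2.88-fold. The 5 that rose, named after their values were seen, were the stefin genes Stfa1, Stfa2 and Stfa3 with log2 fold changes of 1.64, 1.51 and 1.75, Retnlg at 0.99, and the chemokine receptor gene Cxcr2 at 0.95. The median was -0.99 with slide as a block and within slide 1, from CMP replicate 1 alone.

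Genes of mast cells, basophils and eosinophils were lower. Of 10 tested members 4 fell and 6 did not pass, with a median of -0.74 (limma camera adjusted p = 7.32e-05; adjusted p = 0.133 with an estimated correlation), and 7 were lower when adjusted over the list alone. Prss34, a basophil protease, fell 11.9-fold, from -0.91 ± 0.25 to -4.48 ± 0.12 (SD, n = 3), with 1 of 3 CMP arrays well above background. Mcpt8, another basophil protease, fell 3.70-fold. Siglecf fell 2.20-fold and Cpa3, with 1 of 3 CMP arrays well above background, fell 3.12-fold, but under normexp their log2 fold changes were 0.03 and 0.31, and the list no longer passed (median -0.06, adjusted p = 0.149 with limma camera). With slide as a block, and within slide 1, the median was -0.84, from CMP replicate 1 alone.

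Cell cycle genes were lower. Of 32 tested members 4 fell and 28 did not pass, with a median log2 fold change of -1.31 (limma camera adjusted p = 1.92e-11; adjusted p = 0.409 with an estimated correlation, and 0.0602 in limma fry), and 25 were lower when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell 3.47-fold, the mitotic kinase gene Aurkb fell 3.18-fold, Mki67, the proliferation marker, fell 2.75-fold, and Birc5 fell 2.02-fold. The list median against the model mean was -2.0, -0.65 and -1.31 in CMP replicates 1 to 3 and 0.38, 0.10 and -0.46 in model replicates 1 to 3. The median was -0.96 without CMP replicate 1, and -2.0 with slide as a block and within slide 1, where replicate 1 is the only CMP array.

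The antioxidant and glutathione list was lower with an exception. Of 22 members 4 fell, 1 rose and 17 did not pass, with a median of -0.44 (limma camera adjusted p = 0.000776; adjusted p = 0.409 with an estimated correlation); adjusted over the list alone, 9 were lower and 1 was higher. Nqo1, a quinone reductase, fell 5.04-fold, Gsr, glutathione reductase, fell 2.17-fold, and Gstm1 fell 1.87-fold. Hmox1, the haem-degrading enzyme, rose 2.21-fold. Hmox1 also stands in the macrophage list, in which Spic, the transcription factor of red pulp macrophages, rose 1.73-fold. The antioxidant median was -0.61 with slide as a block and within slide 1, from CMP replicate 1 alone.

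**Figure D2:**
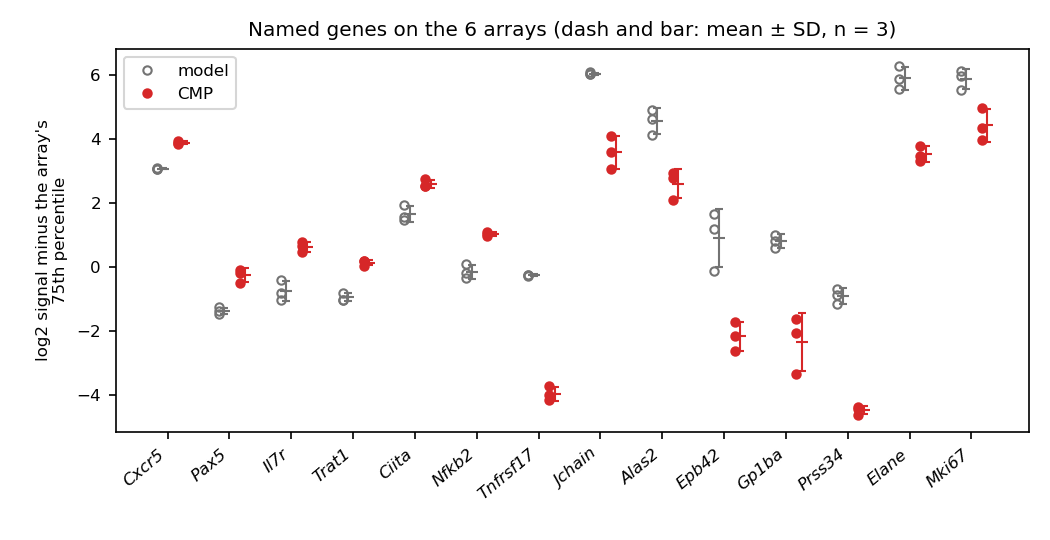
The vertical axis gives the log2 signal minus the 75th percentile of the array for 14 named genes, with open points for the 3 model arrays, filled points for the 3 CMP arrays, and a dash with a bar for the mean ± SD of each group. For Tnfrsf17 the means are -0.26 in model and -3.97 in CMP, and for Il7r they are -0.75 and 0.63.

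The other 13 lists did not pass the limma camera test. Natural killer and cytotoxic genes had a median log2 fold change of -0.26 (limma camera adjusted p = 0.203), and 1 of 18, Nkg7, fell 2.23-fold. The natural killer median turned positive, to 0.17, in CMP replicate 1 alone (slide as a block, and within slide 1). It was 0.23 under normexp, where the median of all genes was 0.20. Without CMP replicate 1 the natural killer list passed with a median of -0.43 (limma camera adjusted p = 0.0316, and 0.767 with an estimated correlation), against -0.02 without CMP replicate 2. Macrophage and monocyte genes had a median of 0.15 with 2 of 20 higher (limma camera adjusted p = 0.542), and 0.29 in CMP replicate 1 alone (slide as a block, and within slide 1). The macrophage median was 0.08 without model replicate 1, 0.24 without model replicate 3, 0.0052 without CMP replicate 1, 0.40 without CMP replicate 2 and -0.04 with probes well above background on all arrays. No dendritic cell gene of 15 passed (median 0.21; 0.33 in CMP replicate 1 alone, 0.0042 without model replicate 1 and 0.50 without model replicate 3). In the stroma and endothelium list Col3a1 and Col6a1, which encode matrix collagens, fell 2.95-fold and 2.23-fold and Cxcl13 rose, among 20 tested; the median was 0.02, the mean -0.04 and the test pointed down, and the median was -0.05 in CMP replicate 1 alone, -0.04 without CMP replicate 3, 0.11 without model replicate 3 and 0.16 under normexp. Adjusted over the list alone, natural killer genes gave 1 lower, macrophage genes 2 higher, dendritic cell genes 2 higher, and stroma genes 1 higher and 2 lower.

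Among signalling and stress lists, few members passed. Of 28 p53 target genes Zmat3 rose 1.65-fold and Trp53inp1 fell 2.40-fold; the median was 0.17, the mean -0.01 and the test pointed up. Of 23 apoptosis regulators Bcl2l1, which encodes a survival protein, fell 2.10-fold (list median -0.09). Of 27 interferon response genes Isg20, a ribonuclease gene, fell 4.01-fold (median -0.03, which turned to 0.03 with median scaling), and without model replicate 3 this list passed with a median of -0.33 (limma camera adjusted p = 0.0283; adjusted p = 0.881 with an estimated correlation), against 0.13 without CMP replicate 2. Of 26 cytokine genes Il18 rose 1.67-fold, Il12a 1.62-fold and Cxcl13 as given, and Ccl3, with 2 of 3 CMP arrays well above background, fell 2.38-fold, although its log2 fold change was 0.14 under normexp (list median 0.07). Of 18 immediate early and heat shock genes Junb rose 2.06-fold and Dusp1 fell 2.07-fold (median 0.20). None of the 14 reference genes passed (median -0.09), although under normexp their list passed with a median of -0.25 (limma camera adjusted p = 0.00822; adjusted p = 0.282 with an estimated correlation). Leaving out single arrays, medians ran from 0.09 to 0.25 for p53 targets, -0.12 to 0.0045 for apoptosis, 0.00068 to 0.17 for cytokines, 0.05 to 0.33 for immediate early and -0.10 to 0.08 for reference genes. The cytokine median was 0.40 under normexp and 0.31 with probes well above background on all arrays, where that of immediate early genes was 0.07; under normexp those of immediate early and apoptosis genes were 0.33 and 0.01. In CMP replicate 1 alone (slide as a block, and within slide 1) the medians were 0.10 for p53 targets, -0.10 for apoptosis, 0.20 for interferon, 0.29 for cytokines, 0.31 for immediate early and -0.08 for reference genes. Adjusted over the list alone, the higher and lower members were 2 and 3 for p53 targets, 2 and 2 for apoptosis, 0 and 1 for interferon, 5 and 4 for cytokines, 2 and 1 for immediate early genes, and 0 and 0 for reference genes.

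Markers of neighbouring organs varied between arrays of the same group. In the liver list 0 of 20 members passed (median log2 fold change 0.85; limma camera adjusted p = 0.107), with medians of 2.26, -1.46 and 1.34 in CMP replicates 1 to 3, the first being also the value with slide as a block and within slide 1. The list passed in limma camera under normexp (adjusted p = 4.23e-06), and without model replicate 1 (0.0223), model replicate 2 (0.0455) or CMP replicate 2 (6.43e-05). With an estimated correlation the limma camera adjusted p was 0.815 on all 6 arrays and 0.210 to 0.842 in these settings. With array weights, a degenerate fit that rests almost wholly on model replicate 2 and CMP replicate 3, the liver median was 1.32. The liver median was 1.75 without CMP replicate 2, 0.25 without model replicate 3, 0.32 without CMP replicate 1 and 0.56 without CMP replicate 3, and the list did not pass in the last 3. Albumin, Alb, had processed signals of 627, 315 and 29 on the model arrays and 1373, 39 and 729 on the CMP arrays. In the adipose list 0 of 14 members passed (median -0.65; limma camera adjusted p = 0.471), and without model replicate 1 the list passed with a median of -1.44 (limma camera adjusted p = 0.00878; adjusted p = 0.829 with an estimated correlation). The adipose median turned positive, to 0.34 in CMP replicate 1 alone, 0.08 under normexp, 0.10 without model replicate 3 and 0.12 without CMP replicate 2. Under normexp it stayed below the median of all genes, which was 0.20 there. Adipsin, Cfd, had signals of 515, 4158 and 6705 in model and 1937, 143 and 1072 in CMP. Of 11 pancreas genes Klk1, with 2 of 3 model arrays well above background, rose 2.33-fold (list median 0.15, and 0.20 in CMP replicate 1 alone; limma camera adjusted p = 0.547). The pancreas median was -0.01 without CMP replicate 3, 0.44 without CMP replicate 2 and 0.52 under normexp. Adjusted over the list alone, no liver or adipose gene and 1 pancreas gene, which was higher, passed.

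The named genes with the largest differences were mostly dim. Of the 12 that rose most, Saa2, an acute phase protein gene, rose 7.18-fold, with an SD of 1.22 among CMP arrays against 0.12 among model arrays. Ldhd rose 4.67-fold, from -4.16 ± 0.25 to -1.94 ± 0.36 (SD, n = 3; limma adjusted p = 0.0106), the lactate receptor gene Hcar1 4.53-fold and Cstdc4 4.14-fold. Mlc1 rose 8.03-fold, Cdh20 7.04-fold, Cadm2 5.69-fold and Zc4h2 3.78-fold, with 2, 1, 1 and 2 model arrays well above background. Not well above background on any model array were Btnl6, at least 3.09-fold higher in CMP, Grin2a, at least 2.78-fold, and Rhbdl2, at least 1.98-fold.

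Of the 12 that fell most, Insl6 was not well above background on any CMP array and was at least 13.5-fold lower there (limma adjusted p = 0.00461). Tac2, a tachykinin precursor gene, fell 24.7-fold with 2 CMP arrays well above background, Tlcd4 fell 16.0-fold with 1, and Fcnb, a lectin gene of immature myeloid cells, fell 9.41-fold with 1. Olr1 was at least 4.19-fold lower, Ly6g6f at least 3.99-fold, Garem1 at least 3.30-fold and Dach2 at least 2.11-fold, none of them well above background on any CMP array, and Dach2 had a log2 fold change of 0.10 under normexp. Hbb-bh1, Tnfrsf17, Prss34 and Sdc1 complete the set. In all, 118 probes were well above background on every model array and no CMP array, and 18 the other way round. The first count was 258 without model replicate 1, 275 without model replicate 3 and 575 without CMP replicate 1. The second was 70 without model replicate 2, 46 without model replicate 3, 175 without CMP replicate 2 and 40 without CMP replicate 3.

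A control probe for the adenoviral E1A sequence, which mouse RNA does not contain, differed between the groups as well. Its log2 signal relative to the 75th percentile was 2.92 ± 1.50 in model and 4.87 ± 0.06 in CMP (SD, n = 3; exact two-sided permutation p = 0.10, the smallest that 3 against 3 allows). Across the 6 arrays 262 tested genes followed this probe within a root mean square of 0.4, among them 234 of the 788 genes at least 2-fold higher at unadjusted p. Of the 402 genes called higher at adjusted p, 0 followed it within that limit. Genes that spread as widely among the model arrays as this probe hardly reach such a call. Among the 12 named genes that rose most, Cdh20, Hcar1 and Cstdc4 lay just outside the limit, at 0.50, 0.53 and 0.57. The others of these lay between 0.61 and 1.23. Leaving out the genes that follow the probe, which was decided after the data were seen, gave 554 genes at least 2-fold higher.

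**Figure D3:**
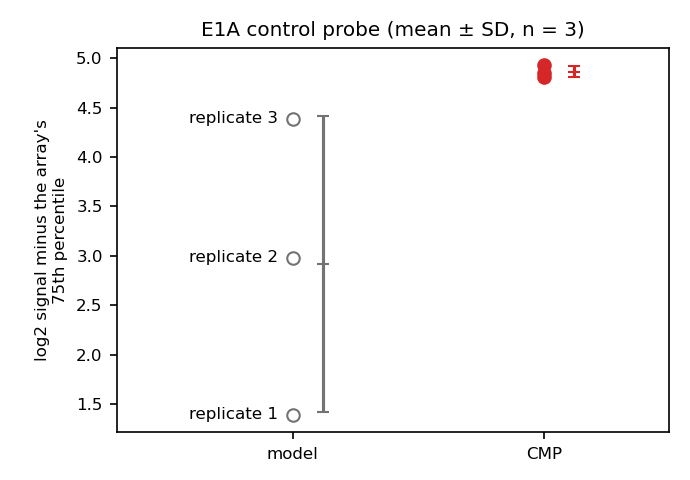
The vertical axis gives the log2 signal of the E1A control probe minus the 75th percentile of the array, with open points for model arrays, filled points for CMP arrays and a dash with a bar for the mean ± SD. The model arrays lie at 1.39, 2.98 and 4.39 and the CMP arrays between 4.82 and 4.93.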

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

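All tests in this part were chosen after the result was seen, and the test of an effect of CMP alone replaced earlier tests whose values had been seen. The E1A control probe carried a signal in data outside the main measurement, and its scaled log2 signal was 1.95 higher in CMP than in model. Its processed signals were 1557, 3552 and 6073 on the model arrays and 12547, 8482 and 10285 on the CMP arrays, and a second E1A probe, well above background on 5 arrays, had 5.92, 20.3 and 45.3 in model and 240, 120 and 144 in CMP, while the other 8 were not well above background on any array.

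Among the genes that follow this probe were Defb36, a defensin gene, Prdm12, Loxhd1 and Tpm3, with log2 fold changes of 1.97, 1.92, 2.17 and 2.21 and limma adjusted p-values of 0.145, 0.133, 0.106 and 0.108. An effect of CMP alone is not excluded, but the test of it cannot decide. It used the 554 genes at least 2-fold higher that do not follow the probe. Their spread among the model arrays exceeded that among the CMP arrays by a median of 0.49 on the log2 scale (95% interval 0.38 to 0.57, from resampled genes). The bound of 0.5 was set with values in view. Removing the genes that follow the probe takes out genes of wide model spread, which lowers this excess. The same measure was -0.08 over all tested genes and -0.13 over the genes at least 2-fold lower. Earlier versions of that test held genes chosen for the pattern: over all 788 genes at least 2-fold higher, 234 of which follow the probe, the excess was 0.95, and over the 262 genes that follow it the spread among model arrays was 2.57 against a group difference of 1.84. Off-target hybridization shared with the control probe is a candidate explanation that these data do not decide: 262 genes followed its profile against at most 2 with the model arrays in another order, but the profile runs along the main axis of all genes, so this comparison of orders decides nothing. What material on the arrays would bind these probes was not tested.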

How the results depend on the processing

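The fits of slide 1 alone, of 2 against 2 arrays and the count without E1A-following genes were chosen after seeing the data; the other settings were planned. Counts of higher and lower genes are limma calls at an adjusted p under 0.05. They were 2 and 33 under normexp, 32 and 218 without a filter on dim probes, 610 and 878 with probes well above background on all arrays, and 5 and 100 with slide as a block. With array weights they were 10865 and 9132, a degenerate fit in which model replicate 2 and CMP replicate 3 had weights of 164 and 259 and the others at most 0.10. The replicate numbers gave no sign of pairing the samples: deviations of same-numbered arrays correlated at -0.13, -0.11 and -0.11, and no array correlated best with its own number. With so few arrays per group this check cannot rule pairing out. With the replicate number as a block limma called 0 higher and 0 lower genes (4486 at unadjusted p under 0.05, smallest adjusted p 0.0509). Slide 1 alone, with 1 CMP array, gave 0 and 0 in limma (5125 at unadjusted p under 0.05), and 2 against 2 arrays gave 0 and 0 (1383), with fewer samples. Leaving out each array gave 0 to 1502 higher and 0 to 1406 lower genes. Quantile normalisation, median scaling, the authors' values, the mean of probes and the trended robust variance stayed within 1.5 times both counts.

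The count of genes at least 2-fold higher was 1271 with array weights, 273 with 2 against 2 arrays, 554 without E1A-following genes and 466 to 1364 leaving out each array. The count at least 2-fold lower was 581 under normexp and 1071 to 1473 leaving out each array. Between 11 and 13 lists passed camera in every setting, and 0 with an estimated correlation. At the preset correlation 4 to 10 lists also passed in splits of the arrays other than the actual one. A steady count of passing lists therefore does not by itself point to CMP. Probes detected in model alone were 126 to 575, and in CMP alone 25 to 175, leaving out each array; with the positive and significant call they were 92 and 43. Of the 1225 called genes 1073 kept their sign under normexp, all 985 measured kept it with probes well above background on all arrays, and at least 1223 kept it elsewhere. The groups of these genes did not overlap. Their sign therefore could not turn in fits that left out or weighted arrays or used a block. Under normexp 5 named genes reversed without passing: Dach2 (0.10), Selp (0.28), Siglecf (0.025), Cpa3 (0.31) and Ccl3 (0.14), and so did the ribosomal protein list's test (median 0.031). Normexp moved the median of all genes from 0.04 to 0.20, and dropping the filter moved it to 0.14, so changes there are relative to that. Why these settings lost calls was not tested; the cause was not tested for the reversals either. Signal over background limits dim genes: 69 lower genes were not well above background on any CMP array and 5 higher genes on any model array.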

Other observations

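The gene groups and the tests in this part were chosen after the data were seen, except the counts over other splits of the arrays; the bounds of the tests on intermediate arrays and on slides were set with the values in view, and 3 of these tests were changed after a first value had been seen.

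Enzymes and transporters of haem biosynthesis were lower in CMP, together with the erythroid list, whose median was -2.34 with 15 of 25 genes lower. Of 12 tested genes 6 fell and 6 did not pass, with a median log2 fold change of -1.76 (limma camera adjusted p = 3.11e-08 over the 6 groups of this part; adjusted p = 0.323 with an estimated correlation), and all 12 were lower when adjusted over the list alone. Cpox fell 6.0-fold, Alas2, which the erythroid list also holds, 3.85-fold, the iron-inserting enzyme Fech 3.40-fold and Urod 2.84-fold. Genes of cholesterol biosynthesis were lower as well: 4 of 18 fell and 14 did not pass, with a median of -0.84 (limma camera adjusted p = 1.66e-07; adjusted p = 0.206 with an estimated correlation), and 14 were lower when adjusted over the list alone. Cyp51, a sterol demethylase, fell 2.94-fold, Stard4 2.07-fold, Msmo1 2.05-fold and Nsdhl 1.92-fold. In CMP replicate 1 alone (slide as a block, and within slide 1) the medians were -1.49 for haem and -0.75 for cholesterol biosynthesis, and both stayed below 0 under every scaling tried, with -0.48 for cholesterol under normexp.

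Collagen genes as a group did not pass (median -0.25 over 25 genes, limma camera adjusted p = 0.222), although Col3a1, Col5a1 and Col6a1 fell by 1.56, 1.55 and 1.16 on the log2 scale. Adjusted over the list alone, 4 were lower and 1 higher. The collagen median was 0.15 under normexp, where that of all genes was 0.20, -0.10 without CMP replicate 1 and -0.04 in CMP replicate 1 alone. No single gene of 79 ribosomal protein genes passed (median 0.26; limma camera adjusted p = 1.61e-05; adjusted p = 0.679 with an estimated correlation), and the call ended with quantile normalisation and with the authors' values (median 0.07 in both, limma camera adjusted p = 0.147 and 0.155), and with normexp (median 0.031, where the test pointed down). The ribosomal median was 0.16 without CMP replicate 2 and 0.08 in CMP replicate 1 alone, and the limma fry adjusted p was 0.218. Of 37 proteasome subunit genes Psmb10, which belongs to the immunoproteasome, had a log2 fold change of 0.58 and passed. The proteasome median was -0.11 (limma camera adjusted p = 0.408), and -0.43 in CMP replicate 1 alone. The list passed limma camera under normexp (median -0.21, adjusted p = 2.61e-06) and without CMP replicate 2 (-0.24, 0.00285). With an estimated correlation the limma camera adjusted p was 0.301 and 0.568 in these settings. With array weights, a degenerate fit that rests almost wholly on model replicate 2 and CMP replicate 3, the proteasome median was -0.15. It was 0.05 without CMP replicate 1 and -0.04 without model replicate 1. No gene of 49 for mitochondrial complex I and cytochrome oxidase passed (median -0.15; limma camera adjusted p = 0.0345; adjusted p = 0.781 with an estimated correlation), and the limma camera adjusted p was 0.103 with median scaling (median -0.10), 0.0560 with the replicate block, 0.144 with 2 against 2 arrays, 0.0723 without model replicate 1 (median -0.10), 0.0611 without model replicate 2, 0.848 without CMP replicate 1 (median -0.03) and 0.0644 without CMP replicate 3. The mitochondrial median was lower still under normexp (-0.27, limma camera adjusted p = 1.53e-10; adjusted p = 0.220 with an estimated correlation), without CMP replicate 2 (-0.25, 1.71e-05; 0.568) and in CMP replicate 1 alone (-0.38), and the limma fry adjusted p was 0.535.

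In each group an array was intermediate: the signals of model replicate 2 lay between those of replicates 1 and 3 for 79.9% of probes, against 11.5% for the next array of the group, and those of CMP replicate 3 lay between the others for 73.7%, against 15.1%. Each probe has a single middle array in a group, so the shares of a group are not separate comparisons. A blend of material is a candidate explanation, with best weights of 0.62 and 0.38 in model and 0.61 and 0.39 in CMP, but the measure is not specific to it: model replicate 2 lay between model replicate 1 and CMP replicate 1 for 69.0% of probes, above the lowest simulated blend, and between model replicate 1 and CMP replicate 3 for 65.5%. A first test was replaced, because spread between single arrays set against technical noise does not settle the cause. It gave residuals of 0.90 in model and 1.30 in CMP times those expected from repeated spots. For model replicate 2 as a blend of model replicate 1 with CMP replicate 1 or 3 the values were 1.76 and 1.69. By this measure the fit of model replicate 2 within its group stood apart from those fits, but it rests on a single array. Separate animals that differ along independent axes stay open, because the test of them cannot decide. In it 8 gene lists placed the intermediate model array within 0.15 of each other (95% interval 0.070 to 0.396, from resampled probes). The CMP array was placed within 0.094 by 16 lists (0.094 to 0.697), with as few as 3 probes a list. Resampling inflates a range of medians from so few probes, and the CMP value lies at the lower end of its interval. These intervals could therefore hardly have excluded such animals. A first version of that test, over 5 lists picked by hand, had given 0.039 in model and 0.047 in CMP, and animals that differ along a single shared axis stay open as well.

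T cell genes were higher while erythroid genes were lower. A smaller share of erythroid RNA that lifts all other cell types alike would not by itself set the other lists apart. The T cell median exceeded that of natural killer and cytotoxic genes by 1.02 on the log2 scale (95% interval 0.61 to 1.62, from resampled genes and not arrays). These medians were 0.67 and 0.23 under normexp and 0.85 and 0.17 in CMP replicate 1 alone. A smaller erythroid share together with fewer natural killer cells would leave the same gap. The test therefore does not exclude a smaller erythroid share as a source of the T cell rise. Slide and treatment cannot be told apart for the slide 2 arrays: CMP replicate 1, on the slide of the model arrays, differed from them in T cell genes by 0.85, which is 0.070 more than the smaller value on slide 2, but it is a single array. A lower share of natural killer cells, treatment with CMP, recovery from cyclophosphamide at different times and the cell make-up of the spleens stay open as untested explanations.

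With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Of these, 1 split, the actual grouping, gave as many calls for each count. It gave 402 higher and 823 lower genes, against at most 0 in the other splits. Genes at least 2-fold higher and lower were 788 and 1292, against at most 494 in either direction. Gene lists passing were 11, against 4 to 10 in the other splits. The splits are not interchangeable, because in each group an array lay between the others. Such an array narrows the spread within its group, which favours the actual grouping. These counts therefore do not measure chance.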
